A study of Oryza sativa with 12 samples.

How the data were processed

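Root tips of the last 5 mm were harvested from rice plants of the varieties Azucena and Bala after 24 days in sand with a layer of 60% wax, per the labels' protocols. The 12 samples form 4 groups of 3 replicates, Azucena before the layer, at it and buckled, and Bala at it. Per the labels' protocols, RNA was extracted with TRIzol and cleaned on columns, and 5 µg of total RNA went through 1-cycle labelling with biotin and onto the Affymetrix GeneChip Rice Genome array. The authors deposited 1 table of array signal intensity values per probe set on a linear scale, made with MAS5 per the submitters' processing notes, which give no version. Other settings of that step are not given in the sources used here. MAS5 sets each probe's match against its mismatch probe and scales each array by 1 factor, so low signals are noisy on a log scale.

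The table holds 57381 probe sets, of which 187 are the manufacturer's controls and were left out of all tests, leaving 57194. A value at or below 0, which occurred 12 times, was set to the smallest positive value of 0.1 before taking log2. The probe sets tested were those with a mean log2 signal over the 12 arrays above the median of that mean (a signal of 5.99), which left 28597. The plan was to keep the deposited scaling unless the arrays' medians differed by more than 0.5. Over all probe sets they ran from 2.96 to 3.7, a difference of 0.74, so arrays were centred, on their median over the tested probe sets, which ran from 5.83 to 6.2. The plan did not say which probe sets the median is taken over. Over the tested ones alone the differences stay under 0.5 and would have left the deposited scaling in place, and centring on all probe sets gives fewer calls between the varieties, so the deposited scaling, both medians and quantile normalisation stand side by side where they change that result.

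Probe sets were named through the array's annotation table and a RefSeq gene table of rice. Of 57194 probe sets, 22436 had 1 gene, 95 several and 34663 none. All 22436 were found in the RefSeq table, and 3194 of them, for 2458 genes, had a gene name there other than a locus number, so most probe sets have only a locus or no name here. No genome sequence was used here, and no coordinates are given because the array's build is not given in the sources used here.

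The tests were limma's linear models on all 12 arrays with 4 group means and moderated variances with a mean trend, two-sided, with Benjamini-Hochberg adjustment over the tested probe sets and a threshold of 0.05. The groups, tests, alternatives and the rule for named genes were fixed before the data were examined. The rule names, per comparison, the 8 largest rises and 8 largest falls among called probe sets with 1 named gene, groups that do not overlap and a higher group above the filter level, and the 2 called members with the largest change of each list that passes camera or has 3 or more calls. Where fewer than 10 probe sets are called it names the 8 with the smallest p. For lists that pass camera with no called member, the 2 members with the smallest p were added, a choice made after no calls were seen.

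Gene lists were tested with camera at a preset correlation of 0.01, with 1 probe set per gene, for lists of at least 5 genes, and again with an estimated correlation and with fry. The lists had been planned as patterns on gene descriptions. The tables used here hold no descriptions, so membership was taken from gene symbols and synonyms, written from the names before any comparison was run. Some planned lists had no members that way, and 29 remained, with 26 large enough to test. The lists cover wall synthesis, hormones, stress, transport, growth and markers of other tissue, and a list holds only the genes that carry a name, so it is a part of its family. The class III peroxidases, auxin transport and synthesis, and diterpenoid phytoalexins were too small. Judging by its fold changes, the list labelled class III peroxidases includes R1C-Prx, a peroxiredoxin, which the plan had meant to exclude. Its counts are therefore not read as class III peroxidases. The sample labels give no batch or scan date.

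Whether replicate numbers pair samples was checked by correlating the deviations of same-numbered arrays from their group means, with a minimum of 0.1 in every pair fixed beforehand. The labels say nothing of shared chambers or days. Between buckled and at tips the 3 correlations were 0.27, 0.15 and 0.25, and each array correlated best with its own number, so these 2 groups were taken as paired from the data. The main fit leaves this pairing out, and only the alternatives with a replicate block use it. Alternatives were quantile normalisation, the deposited scaling, no filter and a stricter filter, offsets of 16 and 64, no mean trend, only the 6 arrays compared, a replicate block, each array left out in turn, a minimum fold and 1 probe set per gene. Centring on all probe sets, the 6 arrays with a block, and leaving out buckled replicate 1 in every comparison were added after seeing the data.

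The scripts were tested on simulated data with 200 probe sets changed among 28597 in each comparison. At 2-fold, 20.9% of changed probe sets were recovered for at against before, 17.9% for each buckled comparison and 22.4% for Bala against Azucena. At 4-fold the shares were 49.3%, 52.2% for buckled against before, 55.2% for buckled against at and 47.8%, and at 8-fold 71.2%, 72.7%, 60.6% and 69.7%. With no list shifted among 15097 genes, camera called 1 of 26 lists for buckled against before and 0 in the others. These simulated genes vary independently, which real genes do not. Analyses used R 4.3.3 with limma 3.58.1, and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.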

Results

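Gene expression was measured in the last 5 mm of rice root tips that met a hard layer of 60% wax in sand. Tips were harvested after 24 days from 2 rice varieties, Azucena and Bala, and total RNA was hybridised to Affymetrix GeneChip Rice Genome arrays, on which a probe set is a group of short probes read as 1 signal. There were 12 arrays in 4 groups of 3. Azucena tips came from roots still 5 to 10 mm above the layer (before), from roots at the layer (at), and from roots that had bent at it and grown 7 to 10 mm further (buckled). Bala tips came from roots at the layer. For arrays, the number per group limits the precision. Each group was independently replicated according to the design text, which does not say whether a replicate is 1 plant or a pool, so p-values measure the spread between these samples. Values are MAS5 signals on a log2 scale, centred between arrays, and are given as mean ± SD with n = 3. Of 57194 probe sets, 28597 were tested, and 3194 of the 57194 carry 1 gene with a name. The 12 arrays correlated at 0.821 to 0.947 over the tested probe sets.

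The first comparison asks how tips that have reached the layer differ from tips still above it. In Azucena the genes of abscisic acid response and dehydration stood higher as a group at the layer by camera at its preset correlation, with 20 of 26 measured genes above their level before it. This did not hold with an estimated correlation (adjusted p = 0.626), and none passed the main test on its own. EM (LOC4338499), a late embryogenesis abundant protein, had a log2 signal of 9.22 ± 2.47 at the layer and 4.16 ± 0.58 before it. The dehydrin RAB21 (LOC4350454) had 10.15 ± 3.09 and 5.22 ± 1.41. With the replicate number as a block, an alternative to the main fit, limma called EM (adjusted p = 0.00952), RAB21 (0.0402) and RAB16B (LOC4350453, 0.00451). These 2 groups did not meet the minimum set for pairing by replicate number, so the block calls are not taken as support. The metallothionein MT2C (LOC4337596) had 4.79 ± 1.92 and -0.63 ± 1.35, the latter near the lowest signals of the array. Heat shock proteins also stood higher by camera at the preset correlation but not at an estimated one (adjusted p = 0.298), with 27 of 41 genes up, among them HSP17.9A (LOC4332357) at 9.05 ± 1.3 against 7.3 ± 0.16 and HSP16.9A (LOC4325697) at 5.17 ± 1.4 against 2.94 ± 0.46.

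In this comparison limma called 0 of the 28597 probe sets at a Benjamini-Hochberg adjusted p of 0.05, with 1471 at an unadjusted p under 0.05 where 1430 are expected by chance. The smallest adjusted p was 0.327. The groups did not overlap for 11.9% of probe sets, where chance gives 10%. The 8 named genes with the smallest p all had higher values at the layer. Beside MT2C, EM and RAB21 these were R1C-Prx (LOC4344045, 16-fold), SCAMP4 (LOC4333331), at 4.49 ± 0.53 against 1.03 ± 1.92, HOX12 (LOC4331956), a homeodomain transcription factor, at 5.85 ± 0.76 against 2.45 ± 1.42, IAA9 (LOC4331061, 4.24-fold), an auxin response repressor, and OsC3H2 (LOC4327304, 3-fold). Their adjusted p from limma ran from 0.36 to 0.829. The means of MT2C, SCAMP4 and HOX12 before the layer lie below the filter level of 2.58, so no fold is given, and with 16 added to each signal their log2 fold changes were 1.56, 1 and 1.72. Without Azucena at replicate 3 the call changed for 10 probe sets, all higher at the layer, among them EM, RAB21, MT2C and IAA9, each at an adjusted p of 0.0383 from limma, and HSP17.9A at 0.0446. The fold of R1C-Prx was 7.31 without before replicate 1 and 26.9 without before replicate 2, and that of IAA9 6.87 without at replicate 3.

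Of 26 gene lists tested with camera at its preset correlation, 6 passed at the layer against before it, and none of the 6 held with an estimated correlation (smallest adjusted p = 0.298). The dehydration list had a median log2 fold change of 0.21 (adjusted p = 0.000949) and the heat shock list 0.14 (0.000949). The pathogenesis-related list, with chitinases and germins, had a median of 0.35 with 14 of 16 genes up (0.0322), among them a chitinase (LOC4351188) at 7.03 ± 1.08 against 4.64 ± 0.94, while the germin-like GER4 (LOC4327911) had 10.14 ± 0.13 against 10.67 ± 0.35. The array's control probe set Mgr-ef1a-3 read 79.8, 41.2 and 1.8 at the layer and at most 1.6 before it. The auxin response list had 34 of 49 genes up (0.0374), with ARF23 (LOC4350610) at 8.4 ± 0.72 against 7.54 ± 0.28. Cellulose synthases and relatives had a median of -0.30 with 29 of 39 genes down (0.00577), including CSLF6 (LOC4344719) at 10.47 ± 0.33 against 11.07 ± 0.45, while CSLE2 (LOC4330583) had 4.56 ± 0.49 against 2.57 ± 1.42, the latter below the filter level. The cytoskeleton list had 33 of 41 genes down (0.00778), with the actin depolymerising factors ADF6 (LOC4336623) at 3.8 ± 0.14 against 4.85 ± 0.09 and ADF1 (LOC4330233) at 6.3 ± 0.31 against 6.9 ± 0.42. With an estimated correlation the adjusted p was 0.298 for heat shock, 0.626 for dehydration, 0.364 for cellulose synthases and 0.53 for the other three lists. Adjusted over the list alone, 2 dehydration probe sets and 1 each of the auxin response and redox lists were called higher and 1 of the xylem wall lower. Of the list labelled class III peroxidases, which appears to include the peroxiredoxin R1C-Prx, 1 was called higher and 1 lower. Over all probe sets 0 were called.

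Other settings ended 2 of these list calls. The pathogenesis-related list had an adjusted p of 0.0767 after quantile normalisation, 0.0875 as deposited, and 0.0711 and 0.148 with 16 or 64 added to each signal, and the auxin list 0.054 as deposited and 0.0592 and 0.0528 with these offsets. Single arrays decided several list calls as well. Without at replicate 1 the dehydration list had an adjusted p of 0.0525, the auxin list 0.381 and the pathogenesis-related list 0.223. The auxin list also had 0.0951 without at replicate 2, 0.108 without before replicate 1 and 0.226 without before replicate 3. The pathogenesis-related list also had 0.0645 without before replicate 1 and 0.357 without before replicate 3. Without before replicate 1 the cytoskeleton list had 0.0596, and without before replicate 2 or at replicate 3 the cellulose list had 0.201 or 0.0528. The actin control's ratio of 3′ to 5′ signal, a measure of RNA integrity, was 18.1, 7.9 and 5.6 before the layer and 26.3, 13.8 and 13.3 at it. It was thus higher at the layer in each replicate number, and whether RNA integrity contributes to the list shifts was not tested. The plot of list means by array shows the spread of the dehydration list within each group.

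**Figure D1:**
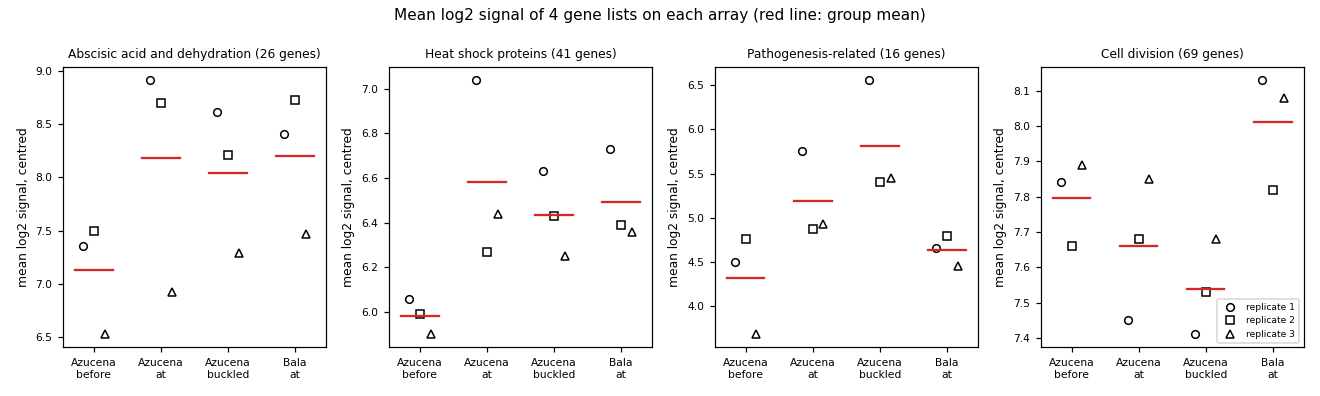
Mean log2 signal, centred on the array median, of 4 gene lists on each of 12 arrays, by group, with 1 point per array, a symbol per replicate number and a red line at the group mean. The dehydration list lies lowest in replicate 3 of each group, for example at 6.92 at the layer where replicates 1 and 2 have 8.92 and 8.7.

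The next comparison asks how tips that have bent and grown on differ from tips above the layer. By camera at its preset correlation pathogenesis-related genes stood higher as a group after buckling, with 14 of 16 up and a median log2 fold change of 1.21, and cell division genes stood lower, with 58 of 69 down and a median of -0.33. Neither held with an estimated correlation (adjusted p = 0.147 and 0.368). The germin-like GER7 (LOC4334487) had a log2 signal of 3.84 ± 0.86 against 1.19 ± 0.72, and the chitinase Cht2 (LOC4349267) 5.18 ± 1.11 against 2.15 ± 1.92. The mitotic cyclin CycB1-1 (LOC4326914) had 4.96 ± 0.64 against 5.99 ± 0.27, and the kinesin KCH1 (LOC4352456) 6.41 ± 0.36 against 7.23 ± 0.24. No gene passed the test on its own.

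Here limma called 0 of 28597 probe sets, with 2428 at an unadjusted p under 0.05 against 1430 expected. The groups did not overlap for 13.8% of probe sets, where chance gives 10%. The 8 named genes with the smallest p all had higher values after buckling. MT2C had 5.69 ± 1.33 against -0.63 ± 1.35 (limma adjusted p = 0.118), and RAA1 (LOC4326229) 8.22 ± 1.77 against 3.59 ± 1.01 (0.352). The others were SCAMP4, at 4.98 ± 1.38, and HOX12, at 5.87 ± 1.26, both against means below the filter level, the glutathione S-transferase GSTZ5 (LOC4332455, 3.74-fold), the ethylene signalling factor EIL1B (LOC4332697, 3.32-fold), mdr17 (LOC4324720, 3.25-fold) and TGAL6 (LOC9270267, 2.55-fold), with adjusted p of 0.362 to 0.416 from limma. Without before replicate 2, 2 unnamed probe sets were called higher, 1 of them at LOC4347963 with a log2 fold change of 5.22 ± 0.58 (SE). With the replicate number as a block limma called 13, all higher, among them MT2C (adjusted p = 0.015), RAA1 (0.00659) and EM (0.0443). These groups too did not meet the minimum set for pairing, so the block calls are not taken as support.

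Camera at its preset correlation called 11 of 26 lists after buckling against before the layer, and none of the 11 held with an estimated correlation (smallest adjusted p = 0.147). Auxin response came first by p, with 37 of 49 genes up and a median of 0.16 (adjusted p = 6.93e-05), with IAA9 at 7.31 ± 0.36 against 5.46 ± 0.34 and ARF23 at 8.65 ± 0.18 against 7.54 ± 0.28. Cell division (0.000114) and pathogenesis-related proteins (0.000139) followed. The cytokinin list had 19 of 25 genes up (0.00268), including LOG (LOC4324445) at 5.28 ± 0.43 against 4.21 ± 0.27 and LOGL9 (LOC4347769) at 3.64 ± 1.24 against 1.53 ± 0.52, both named for enzymes that activate cytokinin. Dehydration had 20 of 26 up (0.00268), with EM at 7.86 ± 1.27 against 4.16 ± 0.58, and heat shock 29 of 41 up (0.00287), with the heat stress factor HSFA4D (LOC4339409) at 5.02 ± 0.43 against 2.54 ± 1.54. The endodermis list had 15 of 19 up (0.0118), with the CASP-like OsCASPL2A1 (LOC4335371) at 5.1 ± 0.16 against 4.21 ± 0.3 and OsCASPL2B1 (LOC4352337) at 5.53 ± 0.96 against 4.28 ± 0.78. Whether CASP-like genes mark the endodermis was not checked here. Redox and detoxification had 32 of 47 up (0.0123). Ethylene synthesis and signalling had 8 of 10 up (0.0259), with EIL1A (LOC107276358) at 11.21 ± 0.42 against 10.73 ± 0.2. Shoot photosynthesis genes had 9 of 10 up (0.032), with LIR1 (LOC4326442) at 4.65 ± 0.62 against 0.55 ± 0.77 and CAB2R (LOC4324599) at 5.19 ± 1.03 against 3.68 ± 0.76. Ion and nutrient transport had 38 of 62 up (0.039), with the zinc and iron transporters ZIP4 (LOC4344937) at 6.3 ± 0.44 against 4.79 ± 0.5 and ZIP6 (LOC4337908) at 7.39 ± 0.37 against 6.57 ± 0.13. With an estimated correlation the adjusted p was 0.147 for auxin, cytokinin, pathogenesis-related, heat shock and ethylene genes and 0.266 to 0.428 for the other 6 lists. Adjusted over the list alone, 4 redox probe sets and 1 each of the pathogenesis-related, ethylene, photosynthesis and cellulose synthase lists were called higher, against 0 over all probe sets.

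The auxin, cell division, pathogenesis-related, cytokinin, dehydration and heat shock calls of this comparison held when any 1 array was left out. Without buckled replicate 1 the redox and ethylene lists each had an adjusted p of 0.0596 and the photosynthesis list 0.092. The photosynthesis list also had 0.0502 without before replicate 1 and 0.0955 without before replicate 2. Without before replicate 3 the endodermis list had 0.28 and the ethylene list 0.0542. The ion list had 0.0618 and 0.0687 without buckled replicate 2 or 3, and 0.327 and 0.0884 without before replicate 1 or 3. Under quantile normalisation, as deposited and with 64 added to each signal the ion list had 0.202, 0.0852 and 0.0638 and the photosynthesis list 0.206, 0.0852 and 0.0652, and the ethylene list had 0.0678 with the mean over a gene's probe sets. Centred on the median of all probe sets, which moves the median fold change of the tested probe sets from -0.06 to -0.36, camera called 19 lists. Buckled replicate 1 had an actin 3′ to 5′ ratio of 54.5, where the other arrays had 5.4 to 31.1. The control Mgr-ef1a-3 read 118, 51.7 and 0.6 in the 3 buckled arrays and at most 1.6 before the layer.

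The third comparison within Azucena sets tips that have buckled against tips at the layer. By camera at its preset correlation genes of phenylpropanoid and lignin synthesis stood higher as a group after buckling, with 21 of 26 up and a median log2 fold change of 0.44, as did aquaporins, with 17 of 21 up and a median of 0.42, and genes of the xylem secondary wall, with 15 of 16 up and a median of 0.52. None of the 3 held with an estimated correlation (adjusted p = 0.216, 0.321 and 0.321). Against before the layer their medians were -0.19, -0.12 and -0.37 at the layer and 0.14, 0.27 and 0.16 after buckling. None passed camera after buckling against before (adjusted p = 0.0876, 0.0876 and 0.331), so a rise above the level before the layer is not shown. PAL (LOC4330034), the entry enzyme of phenylpropanoid synthesis, had a log2 signal of 11.59 ± 0.18 against 10.89 ± 0.03, and 4CL3 (LOC4328485) 6.62 ± 0.11 against 5.38 ± 0.34. The water channels PIP1-1 (LOC4330248) and PIP1-2 (LOC9270874) had 11.69 ± 0.12 against 11.16 ± 0.21 and 12.42 ± 0.33 against 11.97 ± 0.44. GT43A (LOC4337665) had 9.15 ± 0.15 against 8.74 ± 0.12, and LAC7 (LOC4324802) 4.38 ± 0.31 against 2.16 ± 1.93. No gene passed the test on its own.

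For this pair limma called 0 of 28597 probe sets, with 1121 at an unadjusted p under 0.05, fewer than the 1430 expected, and a smallest adjusted p of 0.433. The groups did not overlap for 11.1% of probe sets, where chance gives 10%. By smallest p the named genes with higher values after buckling were AT7 (LOC4337975, 1.77-fold), the sugar transporter SWEET1A (LOC4324848), at 4.51 ± 0.28 against 2 ± 1.36, which is below the filter level, PAL (1.62-fold), ZIP1 (LOC4326394, 4.18-fold) and TPP4 (LOC4330753, 2.66-fold). Those with lower values were R1C-Prx (5.96-fold), MRL7 (LOC4327529, 1.74-fold) and OsPP2C16 (LOC107276004, 2.24-fold). All 8 had a limma adjusted p of 0.961, and the fold of ZIP1 was 2.77 without at replicate 2. Arrays of these 2 groups that share a replicate number deviated together, which the main fit behind the values above leaves out. With the number as a block the 12-array fit called 0 probe sets and the fit of only these 6 arrays called 5. Named here after their values were seen, the 5 were RAB16B (LOC4350453), a dehydrin, with a log2 fold change of -1.41, LOC4324175 (-2.18), LOC4342941 (1.31), LOC4350963 (1.4) and LOC4332695 (1.32).

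Camera at its preset correlation called 14 of 26 lists in this comparison, and none of the 14 held with an estimated correlation (smallest adjusted p = 0.216). Phenylpropanoid genes had an adjusted p of 0.000119, aquaporins 0.000746, ion and nutrient transport 0.000746 with 44 of 62 up, the xylem wall 0.000753, endodermis 0.00145 with 16 of 19 up, and shoot photosynthesis 0.00297 with 9 of 10 up. Among these, ZIP2 (LOC4333098) had 4.13 ± 0.77 against 1.78 ± 1.13, OsCASPL5B2 (LOC4338988) 6.72 ± 0.17 against 6.22 ± 0.18, OsCASPL1C2 (LOC4338204) 5.31 ± 1.6 against 3.8 ± 0.66, petC (LOC4343570) 4.58 ± 0.62 against 1.81 ± 2.74 and PORB (LOC4349004) 3.62 ± 0.46 against 1.16 ± 2.02. Auxin response had 35 of 49 up (0.0065), with IAA17 (LOC4338160) at 11.7 ± 0.19 against 11.29 ± 0.12 and IAA2 (LOC4326775) at 6.62 ± 0.74 against 5.82 ± 0.66. Expansins, which loosen the wall, had 17 of 23 up (0.00655), with EXPA16 (LOC4341549) at 7.53 ± 0.32 against 6.83 ± 0.09 and EXPB11 (LOC4330213) at 9.68 ± 0.47 against 8.98 ± 0.53. Cellulose synthases and relatives had 26 of 39 up (0.0114), with GLU10 (LOC4330667) at 6.24 ± 0.34 against 5.48 ± 0.41 and CSLD2 (LOC4339895) at 9.08 ± 0.4 against 8.68 ± 0.06. After buckling against before the layer the median of this list was -0.065. Pathogenesis-related genes had 12 of 16 up (0.0164), with GER2 (LOC4344839) at 5.07 ± 0.7 against 3.66 ± 0.35 and GER1 (LOC4344840) at 4.57 ± 1.47 against 3.45 ± 0.49. The control Mgr-ef1a-3 read 118, 51.7 and 0.6 in the buckled arrays and 79.8, 41.2 and 1.8 at the layer.

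Jasmonate had 21 of 25 up (0.0285), with OPR10 (LOC4340486) at 8.98 ± 0.46 against 8.14 ± 0.36 and OPR5 (LOC4340485) at 5.8 ± 0.91 against 4.82 ± 0.82. Calcium and touch had 49 of 69 up (0.0384), with CML9 (LOC4339171) at 5.3 ± 0.74 against 4.19 ± 0.58 and CPK5 (LOC4330351) at 8.88 ± 0.11 against 9.16 ± 0.13. Cytokinin had 16 of 25 up (0.0397), with LOGL5 (LOC4334848) at 4.66 ± 0.11 against 3.59 ± 1.01 and ORR4 (LOC4328516) at 9.43 ± 0.28 against 9.03 ± 0.41. Cell division had 51 of 69 down (0.00655), with CycB1-1 at 4.96 ± 0.64 against 5.73 ± 0.3 and RFC4 (LOC4336704) at 8.12 ± 0.06 against 8.48 ± 0.23. With an estimated correlation the adjusted p was 0.216 for phenylpropanoid, ion transport, photosynthesis and expansin genes and 0.272 to 0.493 for the others. Camera called 7 lists without at replicate 3, among the losses aquaporins (adjusted p = 0.0825), the xylem wall (0.12), cellulose synthases (0.0838), auxin response (0.423) and cell division (0.423). It called 6 lists without buckled replicate 1, the array with an actin 3′ to 5′ ratio of 54.5, among the losses photosynthesis (0.0771), expansins (0.071) and pathogenesis-related genes (0.543). The jasmonate, calcium and cytokinin calls were lost without either of these arrays, with adjusted p of 0.31, 0.423 and 0.42 without the first. Without at replicate 2 jasmonate had 0.2, calcium 0.12 and pathogenesis-related genes 0.184, without buckled replicate 2 cytokinin had 0.058 and cell division 0.0591, and without buckled replicate 3 calcium had 0.0971 and cytokinin 0.0543. Cytokinin also had 0.0515 after quantile normalisation, 0.0556 with 64 added and 0.0563 with the mean over a gene's probe sets, calcium 0.089 centred on all probe sets and 0.0556 with 64 added, and jasmonate 0.063 with the mean over probe sets. Adjusted over the list alone, 1 probe set of the list labelled class III peroxidases was called lower, against 0 over all probe sets.

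The last comparison sets the 2 varieties side by side at the layer, the only position sampled in both. Many single genes differed. Each is named here by its called probe set with the largest change, and its other probe sets are not shown. By this design a difference in expression cannot be told apart from a difference in how well the probes match each variety's RNA. BADH2 (LOC4345606), a betaine aldehyde dehydrogenase whose inactive alleles give fragrant rice, was 12.6-fold higher in Bala, at a log2 signal of 9.84 ± 0.31 against 6.18 ± 0.41 in Azucena. The aquaporin PIP2-4 (LOC4343119) was 10-fold higher, at 9.86 ± 0.56 against 6.54 ± 0.13, and the auxin response repressor IAA3 (LOC4325890) 9.63-fold higher, at 11.79 ± 0.13 against 8.53 ± 0.57. pinA (LOC9268662) was 108-fold lower in Bala, at 5.6 ± 0.29 against 12.36 ± 0.07, and the small heat shock protein HSP18.0 (LOC4325342) 29.2-fold lower, at 5.51 ± 1.52 against 10.38 ± 0.41, or 49.9-fold without Bala replicate 1 and 17.4-fold without Bala replicate 2.

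Limma called 3310 of 28597 probe sets at an adjusted p of 0.05, 1654 higher and 1656 lower in Bala, and 1765 at 0.01. Of these, 2335 differed at least 2-fold, 842 higher and 1493 lower. The groups did not overlap for 30.9% of tested probe sets, where chance gives 10%. The split of directions depended on the scaling. As deposited 2917 were called (781 higher and 2136 lower), centred on the median of all probe sets 2245 (589 and 1656), and after quantile normalisation 2689 (858 and 1831), so the share higher was 50% as centred here and 26.8%, 26.2% and 31.9% under the others. The median fold change of the tested probe sets was 0.18 on the log2 scale as centred here and -0.04, 0.06 and 0.04 under these scalings, so differences are read against that shift. It also depended on other settings. Without Azucena at replicate 1, 2156 were called (815 higher and 1341 lower), without Bala replicate 3, 2222 (791 and 1431), and without Bala replicate 2, 2574 (1075 and 1499). With the replicate number as a block 4820 were called (2837 and 1983), and with 1 probe set per gene 2111 genes (1320 and 791). A stricter filter gave 2999 (1697 higher and 1302 lower) and no filter 2945 (1408 and 1537). With 16 added to each signal 3288 were called (1748 and 1540), and with 64 added 3163 (1796 and 1367).

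**Figure D2:**
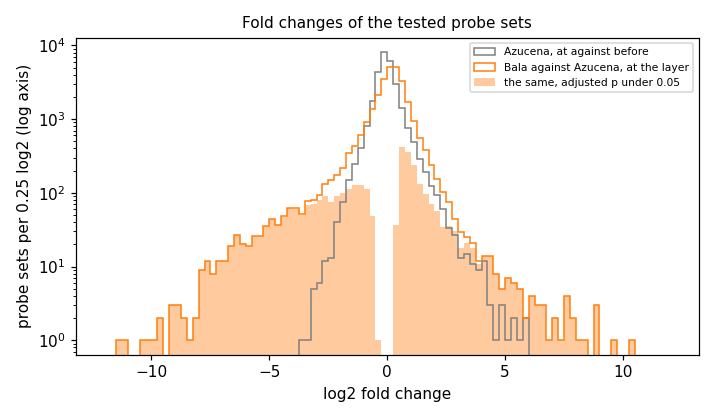
Histogram of log2 fold changes of the 28597 tested probe sets, in bins of 0.25 with a logarithmic count axis, for Azucena at against before the layer (grey) and Bala against Azucena at the layer (orange line). The filled bars are the 3310 probe sets with an adjusted p under 0.05, of which 1022 lie at -2 or below and 311 at 2 or above.

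Of the called probe sets, 276 carry 1 named gene, 191 higher and 85 lower. The largest named rises, beside those above, were OC-X (LOC4335551, 17.5-fold), CARA (LOC4330474, 10.1-fold), which makes carbamoyl phosphate, PP2A4 (LOC4348601, 8.5-fold), the lignin pathway transferase HCT3 (LOC4340333, 8.24-fold) and the beta-glucosidase BGLU9 (LOC9269478, 7.84-fold). Their limma adjusted p ran from 7.89e-05 to 0.0172, HCT3 was 4.79-fold higher without at replicate 1, and BGLU9 lost its call without at replicate 2 (0.0543), at replicate 3 (0.0532) or Bala replicate 2 (0.063). The largest named falls, beside pinA and HSP18.0 above, were Chib3H-h (LOC4351187, 23.7-fold, or 43.7-fold without at replicate 3) and 5 genes whose Bala means lie below the filter level, so that no fold is given. These were the cellulose synthase-like CSLE1 (LOC4347370), at 0.16 ± 1.6 against 6.08 ± 0.6 in Azucena, a chitinase (LOC4351188), at 1.38 ± 1.35 against 7.03 ± 1.08, CCD8A (LOC4327933) of the strigolactone pathway, at 0.72 ± 2.74 against 5.54 ± 0.27, the histone H2B.10 (LOC4324495), at 1.25 ± 1.36 against 6 ± 0.18, and the metallothionein MT2A (LOC4325218), at 2.19 ± 1.27 against 6.6 ± 1.84. With 16 added to each signal their log2 fold changes were -2.15, -2.87, -1.52, -1.97 and -2.43, all called. None of the 5 lost its call when any 1 array was left out.

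**Figure D3:**
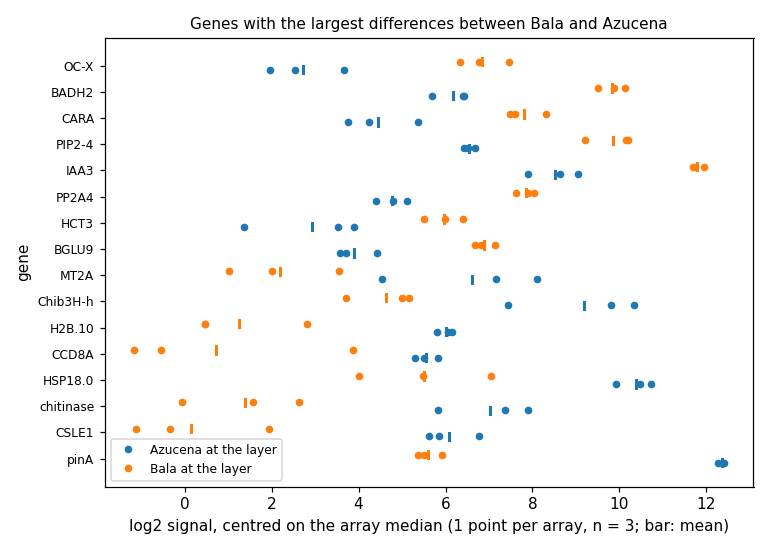
Log2 signal, centred on the array median, of the 16 named genes with the largest differences between Bala (orange) and Azucena (blue) at the layer, with 1 point per array (n = 3) and a bar at each mean. The groups do not overlap for any of the 16, and pinA shows the largest gap, with means of 5.6 and 12.36.

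Over all tested probe sets 11.57% were called, and called probe sets with 1 named gene ran 191 higher to 85 lower. The counts of lists, which hold only named genes, are to be read against both, and the share called among named probe sets alone was not worked out. The shares called of the ion transport, calcium, auxin response, redox and heat shock lists lie near the share over all tested probe sets. By gene list, cell division had 13 probe sets higher and 3 lower of 75 in Bala, and adjusted over the list alone 15 and 3. KIN14B (LOC9267695) was 4.63-fold higher and KIN14R (LOC4352796) 5.81-fold lower, both kinesins. Cellulose synthases and relatives had 8 higher and 2 lower of 46, and over the list alone 12 and 3, with CSLC2 (LOC4347118) 5.69-fold higher. The cytoskeleton list had 6 and 3 of 53, over the list alone 12 and 3, with ADF1 3.16-fold higher and ARP9 (LOC4335089) 4.2-fold lower. Ion and nutrient transport had 7 and 0 of 71, over the list alone 6 and 0, with ZIP8 (LOC4342782) at 4.45 ± 0.41 against 1.82 ± 1.4, which is below the filter level, and the potassium channel AKT1 (LOC4326245) 3.1-fold higher. Phenylpropanoid genes had 4 and 2 of 34, over the list alone 8 and 2, with CAD8C (LOC9269515) 10.6-fold lower. The endodermis list had 4 and 1 of 25, over the list alone 5 and 1, with the CASP-like OsCASPL2C1 (LOC4341716) 4.94-fold and OsCASPL4B4 (LOC4338478) 4.33-fold higher. Calcium and touch genes had 7 and 4 of 84 under both adjustments, with CML31 (LOC4325408) at 1.81 ± 2.04 against 5.91 ± 1.7 and CPK21 (LOC4346187) at 0.46 ± 0.68 against 4.08 ± 0.78, both below the filter level in Bala. With 16 added to each signal the 2 lost their calls, with log2 fold changes of -1.86 (adjusted p = 0.0904) and -0.82 (0.065), and with 64 added they had 0.176 and 0.128. Auxin response had 4 and 1 of 55, over the list alone 1 and 0, with ARF24 (LOC4352211) 2.4-fold higher beside IAA3.

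Redox and detoxification had 4 higher and 3 lower of 70, over the list alone 3 and 3, with the glutaredoxin GRXS1 (LOC4327130) 16.3-fold lower. Heat shock proteins had 3 and 3 of 56 under both, with HSP17.4 (LOC4332360) 10.8-fold lower, and pathogenesis-related genes 1 and 3 of 20 under both. The control Mgr-ef1a-3 read 1, 1.4 and 1 in the Bala arrays and 79.8, 41.2 and 1.8 in Azucena at the layer. The heat shock median of 0.23 and the pathogenesis-related median of 0.28 differ in sign from their means of -0.09 and -0.55. No list passed camera, where the smallest adjusted p was 0.219, for cell division, or 0.97 with an estimated correlation. Fry, which asks whether a list moves one way on balance, passed 1 list, cellulose synthases and relatives (adjusted p = 0.0244). Fry sets fold changes against 0, and the tested probe sets had a median of 0.18 under this centring, so that shift may contribute. Camera, which sets a list against other genes, gave this list an adjusted p of 0.387. The calls of ZIP8, AKT1, OsCASPL2C1, ARF24, CML31 and CPK21 were lost when single arrays were left out, for example without at replicate 1, where their adjusted p were 0.115, 0.0859, 0.0987, 0.0525, 0.15 and 0.132. Other single arrays also ended these calls, for ZIP8 each Bala array (0.0653, 0.0657 and 0.13), for AKT1 at 2 (0.0981) and Bala 2 and 3 (0.0954 and 0.0661), for OsCASPL2C1 at 2 and 3 (0.0641 and 0.0785) and Bala 2 and 3 (0.0822 and 0.126), for ARF24 each of the other 5 (0.0748 to 0.125), for CML31 Bala 3 (0.133), and for CPK21 at 3 (0.098) and each Bala array (0.0521, 0.0648 and 0.116). Under other scalings ARF24 had 0.0612 to 0.13, AKT1 and OsCASPL2C1 had 0.0643 and 0.0659 as deposited, and ZIP8 0.0583 when centred on the median of all probe sets.

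The remaining lists had few called probe sets between the varieties. The jasmonate and gibberellin lists each had 2 lower, the dehydration list 2 higher, and the list labelled class III peroxidases and the phosphate starvation list 1 each way. Cytokinin, aquaporin and cytoplasmic ribosomal protein genes had 1 higher each, and expansin, fermentation, WRKY and meristem genes 1 lower each. Ethylene synthesis and signalling, ethylene-responsive factors, auxin transport and synthesis, diterpenoid phytoalexins, the xylem wall and shoot photosynthesis had 0. Adjusted over the list alone, jasmonate had 1 lower, expansins and meristem genes 0, and the rest of these lists the same counts. Within Azucena no list had a called member, so the overlap of calls between comparisons that share arrays was 0. The fold changes of the at and buckled groups, each against before, correlated at 0.61 across probe sets, which are not independent replicates, where unchanged groups simulated against shared arrays gave 0.5. Their covariance was 0.239 against 0.159 simulated, a difference of 0.08, and the before group has too few arrays to split it. That simulation leaves out the pairing of at and buckled arrays by replicate number. With it, at the mean correlation of 0.22 found between them, a run added after the values were seen, unchanged groups gave r = 0.61 and a covariance of 0.192, and with same-numbered before arrays correlated too (0.13 with at and 0.08 with buckled) 0.56 and 0.159.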

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

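The level for control probe sets and the tests of scaling, replicate number, RNA integrity, buckled replicate 1, the Mgr controls and the share of dividing tissue were chosen after the results they concern were seen, while the test of probe match was not.

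Signal appeared in control probe sets that a rice root tip should leave dark, read against 21.2, the highest signal any of 97 such probe sets had on the 3 arrays before the layer. The control Mgr-ef1a-3, for a gene of an organism that the files abbreviate as Mgr, read 79.8 and 41.2 in at replicates 1 and 2 and 118 and 51.7 in buckled replicates 1 and 2. Before the layer it read at most 1.6. A sister probe set for the same gene read 29.1 in at replicate 1 and 43.9 and 32 in buckled replicates 1 and 2, and one from the middle of the gene read 34 in buckled replicate 1. Reporter controls read 23.3 and 37.1 in buckled replicate 1 and 25 in buckled replicate 2, and the control TagIN-5 read 23.1 in buckled replicate 1. TagIN-5 had itself read up to 21.2 before the layer, which is the level used. These 2 buckled arrays also had the highest median log2 signals over all probe sets, at 3.7 and 3.41, so readings near the level may reflect the arrays' background. Apart from these dark controls, the rice ribosomal RNA controls had a geometric mean of 33.8 in Bala, with each Bala array above the highest before array at 25.3.

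By camera at its preset correlation pathogenesis-related genes stood higher and cell division genes lower after buckling than before the layer, and neither held with an estimated correlation (adjusted p = 0.147 and 0.368), so the pattern itself is weak. Buckled replicate 1, which stood apart from the other arrays, does not account for it alone, since without it the larger camera adjusted p of both lists, again at the preset correlation, was 0.00274. RNA from another organism in the tips may contribute. The deviations of the pathogenesis-related list from group means followed those of Mgr-ef1a-3 with r = 0.59 (permutation p = 0.21, rho = 0.42, permutation p = 0.32, and r = 0.6 without the 2 farthest arrays), which decides nothing. A smaller share of dividing tissue in the harvested tips could lower cell division genes, but meristem regulators had a median log2 fold change of -0.12 with 8 of 14 lower (camera adjusted p = 0.854). The endodermis list had 15 of 19 higher (0.0118, or 0.329 with an estimated correlation). Its members named here are CASP-like genes, which were not checked as markers of that tissue. A change in tissue share stays open too, as does a response to bending itself.

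The mean signal of the dehydration list differed between replicates of a group by up to 2 on the log2 scale and was lowest in replicate 3 in 4 of 4 groups. Whether a round of growth or harvest shared by replicate number lies behind it stays open, because shuffling the numbers within groups (exact permutation p = 0.0324 over 216 arrangements) only restates the order that had been seen. RNA integrity is a candidate explanation, since the list's deviations followed those of the log2 actin 3′ to 5′ ratio with r = 0.62 over 12 arrays (permutation p = 0.0404, rho = 0.69, permutation p = 0.0215, and r = 0.61 without the 2 farthest arrays). Neither is argued against here, the ratio itself may follow the round, and no biological explanation was tested for a spread within groups.

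Between the varieties 1022 probe sets were called at a log2 fold change of -2 or below in Bala and 311 at 2 or above. The ratio of these counts was at least 3.29 under the 4 scalings run, and up to 5, so the choice among these 4 does not account for it. They moved the median fold change of the tested probe sets only between -0.04 and 0.18. Against a cutoff of 2 such shifts could hardly turn the ratio, so the test says nothing of other ways to scale or to treat low signals. Probe sets that match Bala RNA less well than Azucena RNA may lower their signal, in which case other probe sets of the same gene would often not fall with them. Where a gene had another tested probe set, it was called lower too for 45.1% beside a far lower one (97 of 215) and called higher too for 42.4% beside a far higher one (25 of 59, Fisher's exact p = 0.768). That leaves probe match open, as are genes missing or truly less expressed in Bala, since the variety is what the design compares. The filter may also contribute, since it takes the mean over all arrays, most of them from Azucena. It keeps a probe set near the floor only in Bala more readily than the reverse case. Calls of any size turned towards higher in Bala with a stricter filter (1697 higher and 1302 lower) and with 64 added to each signal (1796 and 1367). Without the filter they were 1408 higher and 1537 lower. The balance thus depends on how low signals are treated. Far lower and far higher calls were not compared without the filter, and the test of probe match used filtered probe sets, so this stays open too.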

How the results depend on the processing

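The 6-array fit with a block, centring on all probe sets, and leaving out buckled replicate 1 where a comparison does not hold it were chosen after seeing the data.

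None of the 31 list shifts that passed camera and no named gene reversed direction in the settings run (of the 73 list tests that did not pass, fry gave the other direction in 10, with 0 passing), but the balance of Bala calls turned, from 1654 higher and 1656 lower to between 26.2% higher (centred on all probe sets) and 62.5% (1 probe set per gene). With the replicate number as a block the 12-array fit called 4 probe sets at the layer against before (all higher: EM, RAB21, RAB16B and an unnamed one) and 13 for buckled against before (all higher), and with only the 6 arrays compared and a replicate block 52 (46 higher), 67 (66 higher) and, for buckled against at, 5. For the first 2 comparisons and Bala against Azucena, same-numbered arrays correlated at 0.06 to 0.22, 0 to 0.14 and 0.03 to 0.09. Their own number was best in 2, 2 and 1 of 3 pairs. The minimum of 0.1 in every pair was not met, so these groups were not taken as paired. The labels do not say whether they share a round, which stays open. The block ended no camera call, gave 15 lists for buckled against before, and moved the Bala count to 4820. The cause of the block's effect was not tested. Leaving out single arrays gave 0 to 10 calls for at against before (10 without at replicate 3), 0 to 2 for buckled against before (2 without before replicate 2), 0 for buckled against at, and 2156 to 3606 for Bala against Azucena (2156 without at replicate 1). Fewer arrays lower the degrees of freedom, and beyond that the cause was not tested. With 1 probe set per gene 2111 were called between the varieties, where fewer features were tested. The other settings gave 2245 to 3288 there and 0 in the Azucena comparisons.

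For gene lists, leaving out single arrays gave 3 to 8 for at against before (3 without before replicate 1), 8 to 16 for buckled against before, 6 to 16 for buckled against at (6 without buckled replicate 1 and 7 without at replicate 3) and 0 to 1 for Bala against Azucena (1 without at replicate 3 or Bala replicate 2). Centring on all probe sets gave 19 for buckled against before, and the cause was not tested. An estimated correlation gave 0 in each Azucena comparison, and fry gave 0 there and 1 between the varieties, and the cause was not tested. The other settings gave 4 to 6, 9 to 15, 12 to 15 and 0 lists. Of the named genes' values, 1 per gene and setting, 7 of 221, 3 of 324 and 0 of 408 in the Azucena comparisons gained a call and 39 of 403 between the varieties lost one. Low signals limit the folds of genes near the floor.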

Other observations

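The lists named below and the GAPDH and ubiquitin controls were singled out after their values were seen, while the list tests and the splits were planned.

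Among lists that passed camera in no comparison, genes of oxygen shortage and fermentation had 10 of 12 members up after buckling against before the layer, with a median log2 fold change of 0.35 (camera adjusted p = 0.073), and 9 of 12 up against tips at the layer (0.165). All 5 WRKY factors measured were up after buckling against before, with a median of 0.88 (0.157). Gibberellin genes had a median of 0.39 at the layer against before, with 8 of 12 up (0.212). Cytoplasmic ribosomal protein genes moved little, with medians of -0.009, -0.055 and -0.052 in the Azucena comparisons. None of these passed.

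The 6 arrays of each comparison can be split into 3 and 3 in 10 ways, too few for a share under 0.05. Between the varieties the real split called 3310 probe sets and the highest other 0, so 1 of 10 splits gave as many. At against before and buckled against before, the real split and all others called 0, so 10 of 10 gave as many in each. Buckled against at called 0 and another split, which sets at replicates 1 and 2 and buckled replicate 1 against the rest, called 4, so 10 of 10 gave as many.

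Other splits called many lists with camera. At against before 6 of 10 splits gave as many as the real 6, the highest other being 13, and buckled against before 3 of 10 gave as many as the real 11, the highest other being 15. Buckled against at 1 of 10 gave as many as the real 14, the highest other being 12, and among the 3 other splits that part all 3 pairs the highest was 5. Between the varieties 10 of 10 gave as many as the real 0, the highest other being 12. A camera call at the preset correlation is therefore weak evidence here. Estimated correlations within lists reached 0.656, against the preset 0.01, and whether they or a structure of the samples lie behind the calls of other splits was not tested.

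The 3′ to 5′ ratio of the GAPDH control was 19.8, 8.1 and 4.5 in Bala and 25.8 to 100 in the 9 Azucena arrays, while the actin ratio of the Bala arrays was 31.1, 16.9 and 5.4. In Azucena replicates 1, 2 and 3 the GAPDH ratio was 55.2, 39.4 and 25.8 before the layer. It was 88.5, 41.9 and 34.4 at the layer and 100, 53.4 and 37.4 after buckling, so it rose with position in each replicate number. The ubiquitin ratio was 1.31, 1.09 and 0.95 before the layer and 0.92, 1 and 1.03 at it. Whether RNA integrity contributes to the list shifts between Azucena groups was not tested.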
